A study of Mus musculus with 6 samples.

How the data were processed

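Messenger RNA of mouse pancreatic islets was measured on 6 Agilent 1-colour microarrays, 2 for each of 3 groups. The groups and replicate numbers follow the sample titles, and each scanner file was taken for the sample it is recorded under. Per the labels, total RNA was labelled with Cy3 by Agilent's Low Input Quick Amp kit. Nothing in the labels says that the 2 arrays of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

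Per the file headers, the authors read each array with Feature Extraction 10.7.3.1 under the manufacturer's protocol for 1-colour expression arrays, on array design 026655. The deposited scanner files give each spot's processed intensity, which is background-subtracted, detrended and floored but not scaled between arrays, together with the median intensity of the spot and of its local background. Flags for spots well above background, saturated spots and outlier spots come as 0 or 1 in the same deposited files. The authors also deposited a table of log2 values whose scaling is not given in the sources used here. Its differences between columns equalled differences of log2 processed intensity scaled to each array's 75th percentile (slope 1.0), and each probe was centred on its median over the 6 arrays. That table held 39485 probes, with column medians of 0.087 and 0.141 for TrspFF, 0.011 and -0.029 for Trsp-RIPKO, and -0.079 and -0.045 for Trsp-Ins1KO.

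The names of 4 columns of the authors' table went against the scanner files. Over 9165 probes, the columns named TrspFF followed the scanner files of Trsp-Ins1KO (r = 1.0) and not their own (r = -0.306 and -0.539), the columns named Trsp-Ins1KO followed the scanner files of TrspFF, and the Trsp-RIPKO columns followed their own. Which source holds the right names is not given in the sources used here. The main results use the groups of the scanner files, and the table served as an alternative both with its columns taken by the matching scanner file and with its own names.

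From the processed intensity, log2 values were computed and each array's 75th percentile was subtracted. Control spots (1377) and outlier spots were left out of 43020 non-control spots, spots of 1 probe were averaged, and 3 of 39429 probes with no usable spot on some array were dropped, leaving 39426. RefSeq accessions of the array annotation named 26053 probes (66.1%) through a table of the GRCm38.p6 assembly, which was used for names only, and other probes kept the name in the file. No coordinates are given, since the array annotation and that table rest on different builds. A probe entered where it was well above background on all arrays of at least 1 group. Each gene was represented by the entering probe with the highest mean over the 6 arrays, so that 23199 probes gave 19021 genes, 13370 of them with a gene symbol. No probe for Trsp was found in the annotation, so the targeted gene could not check the labels.

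Groups were compared in limma 3.58.1 (R 4.3.3) with a mean per group, lmFit and eBayes over all 6 arrays, which gave 5.1 total and 2.1 prior degrees of freedom. The contrasts were each knockout against TrspFF, Trsp-Ins1KO against Trsp-RIPKO, and the mean of both knockouts against TrspFF. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Values are log2 differences with the standard error (SE) of the fit. For a gene whose probe was well above background on no array of the dimmer group, a bound was computed as well: the brighter group's mean against the dimmer group's mean of, per array, the higher of the lowest signal among probes well above background and the gene's own signal. Such bounds are written "at least N-fold". No fold is given where a bound came under 1 or where the probe was well above background on no array of either group, and list medians were also computed with members at their bound. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 served for reading, checks and plots.

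The design, the alternatives and 32 gene lists were fixed before the data were examined. The lists cover selenoproteins, selenocysteine machinery, NRF2 targets, other antioxidant enzymes, the integrated stress response, the unfolded protein response, p53 targets and apoptosis, DNA damage repair, senescence, immediate early and heat shock genes, hypoxia and glycolysis, nuclear-encoded oxidative phosphorylation, fatty acid oxidation, fatty acid synthesis and lipogenesis, cholesterol synthesis, cell cycle, NF-kB and cytokine response, interferon response, growth hormone, prolactin and STAT5 response, exocytosis and ion channels, beta-cell identity, disallowed and dedifferentiation genes, and markers of alpha, delta, PP and epsilon cells, acinar cells, duct cells, endothelial cells, fibroblasts and stellate cells, macrophages and dendritic cells, T and B cells, Schwann cells and neurons, erythrocytes, and adipocytes. Of these, 31 had at least 5 tested members and were tested with camera at its preset correlation of 0.01, adjusted over 124 tests (31 lists in 4 contrasts). None of the 40 calls over the 4 contrasts held with a correlation estimated per list: 0 lists were called in each. Lists of liver genes, small intestine genes, and Xist with Y-linked genes were added after seeing the data.

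Named genes follow a rule. For each contrast they are the 12 genes with the largest positive and the 12 with the largest negative change among called genes with a symbol that were well above background on every array of the higher group. Hormone genes, Tph1, Tph2, Gh, Prlr and every selenoprotein were always to be named where tested (Tph2 was well above background on no array and Gh on 1 Trsp-RIPKO array, so neither was tested). Other examples from the lists were chosen after their values were seen and before the alternatives were run. In all, 259 gene values were recomputed under each alternative. Of these, 1 value is counted but not reported here.

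Alternatives were normexp background correction (offset 50), quantile normalization, median scaling, no filter on dim probes, only probes above background on all 6 arrays, every probe on its own, the mean over the probes of a gene, eBayes with trend and robust, only the groups of the contrast, the authors' table, the replicate number as a block, fry, camera with an estimated correlation, and leaving out each array in turn. For normexp, the median spot intensity replaced the mean, a column not used here. Its offset weighs most on the dim Trsp-Ins1KO arrays (75th percentile 121.9 and 110.7). Normexp therefore cannot settle directions of genes dim there. Alternatives added after seeing the data were the table's own column names, the 2 TrspFF arrays averaged as 1 sample, and leaving out 576 genes on X and Y or in the acinar, liver and intestine lists. A slide block was not run for contrasts with Trsp-RIPKO, whose 2 arrays alone filled slide 2.

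The fit was tested on simulated data with 200 of 19021 genes changed in each of 5 runs. For Trsp-RIPKO against TrspFF it recovered 9.9%, 82.7% and 97.6% of changes of 0.5, 1 and 2 on the log2 scale. The same shares were 12.2%, 86.3% and 97.3% for Trsp-Ins1KO against TrspFF, and 15.2%, 83.9% and 97.3% for Trsp-Ins1KO against Trsp-RIPKO. False calls per run averaged 6.4, 7.8 and 8.2, with 0 wrong signs. A list shifted by 0.5 was called in 5 of 5 runs of each contrast, also with an estimated correlation, and lists that were not shifted were called 2 times over the 5 runs of Trsp-RIPKO against TrspFF and 0 times in the other contrasts. In these runs genes varied independently, whereas list members in the data had estimated correlations of up to 0.287 (hypoxia and glycolysis). The runs therefore do not test list calls under such correlation. With 200 changed genes the adjusted threshold was also stricter than in the data, where 6921 to 8737 genes were called. The recovered shares thus do not give the power there. The number of arrays limits the precision of all values.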

Results

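The data comprise 6 microarrays of pancreatic islets from mice that the labels give as male, 16 weeks old and of ICR background. Trsp encodes the transfer RNA that delivers selenocysteine, the amino acid on which selenoproteins depend. In TrspFF islets the gene was floxed and no Cre was present, in Trsp-RIPKO islets Cre was driven by a rat insulin promoter, and in Trsp-Ins1KO islets Cre came from the Ins1 line. Each group held 2 arrays. The series' own design text ties loss of Trsp to oxidative stress, so the comparisons ask how the islet mRNA of each Cre line differed from floxed controls and from the other line.

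The 75th percentile of processed intensity was 247.2 and 218.1 on the TrspFF arrays, 215.2 and 203.0 on the Trsp-RIPKO arrays, and 121.9 and 110.7 on the Trsp-Ins1KO arrays. Probes well above background made up 57.9% and 57.5%, 57.9% and 61.0%, and 52.2% and 51.4% in the same order, and 0 probes were saturated. Spike-in controls lay 4.1 and 4.33 (log2) above the 75th percentile in TrspFF, 4.36 and 4.47 in Trsp-RIPKO, and 5.55 and 5.57 in Trsp-Ins1KO. The scanner software's quality status was in range for TrspFF and Trsp-Ins1KO and marked for evaluation for both Trsp-RIPKO arrays. Both arrays of a group differed by an SD of 0.089 (TrspFF), 0.139 (Trsp-RIPKO) and 0.15 (Trsp-Ins1KO) on the log2 scale, against 0.366 to 0.499 between groups. Probes spotted at least 8 times showed that the arrays of a pair differed by 2.11, 3.31 and 4.37 times what spot noise gave. Spot noise leaves out labelling and hybridisation, so these ratios do not show that the RNA came from separate animals. TrspFF and Trsp-Ins1KO shared slide 1, and the Trsp-RIPKO arrays alone filled slide 2, so that slide and group cannot be told apart for Trsp-RIPKO.

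Every direction given here follows the scanner files. In the authors' table the columns named TrspFF and Trsp-Ins1KO hold each other's values. Under its names each change of Trsp-Ins1KO against TrspFF has the opposite sign. Under those names, Trsp-RIPKO would be compared with the arrays filed here as Trsp-Ins1KO. Its list calls for selenoproteins (camera adjusted p = 0.62), oxidative phosphorylation (0.91), acinar cells (0.15), dedifferentiation (0.28), other antioxidant enzymes (0.096) and erythrocytes (0.84) were lost under them. The stress response (2.7e-10) and endothelial (0.0045) lists were then called lower, and the cell cycle, fibroblast and hypoxia lists kept their calls. Newly called were NRF2 (0.00019), immediate early and heat shock (0.0047), beta-cell (0.0087), senescence (0.034) and exocytosis lists (0.047), lower, and interferon (0.0034), higher.

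Trsp-RIPKO islets carried lower mRNA of several selenoproteins than TrspFF islets. They carried higher mRNA of acinar enzymes, intestinal genes, cell-cycle genes and genes of the dedifferentiation list. Gpx4, which reduces lipid hydroperoxides, fell by 0.79 on the log2 scale (SE 0.078, n = 2 arrays per group, limma adjusted p = 0.00579), and Selenoh, a nuclear selenoprotein, fell by 0.83 (SE 0.075, adjusted p = 0.00484). Gpx2, the glutathione peroxidase of the gut lining, rose by 0.90 (SE 0.067, adjusted p = 0.00362). Aldh1a3, a retinaldehyde dehydrogenase known from dedifferentiated beta cells, rose by 2.86 (SE 0.085, adjusted p = 0.000499). Xist, the RNA that silences an X chromosome in female cells, was present on the TrspFF and Trsp-RIPKO arrays and rose by 1.63, while the Y-linked Ddx3y and Eif2s3y fell by 1.36 and 1.13.

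Of 22 tested selenoproteins, 13 fell, 2 rose and 7 did not pass in Trsp-RIPKO against TrspFF (14 fell and 3 rose adjusted over the list alone). The list's median change was -0.35. Its call (camera adjusted p = 0.02) was lost with an estimated correlation (0.58), quantile normalization (0.084) and median scaling (0.053). Selenot of the endoplasmic reticulum (-1.04) and Gpx1 (-0.74), the main cytosolic glutathione peroxidase, were among those that fell. Smaller falls were called for Selenoo (-0.44), Selenok (-0.41), Selenow (-0.40), Selenoi (-0.38), Selenof (-0.36), Selenos (-0.36), Dio1 (-0.35), Selenop (-0.34) and Gpx3 (-0.34), and a rise for Selenov (0.55). With median scaling these smaller falls grew to between -0.57 (Selenop) and -0.68 (Selenoo), and Selenov came to 0.31. Not past the threshold were Sephs2 (0.59), Txnrd3 (-0.42), Msrb1 (0.13), Selenon (0.13), Selenom (-0.05), Txnrd1 (-0.03) and Txnrd2 (0.02). Of these, Txnrd3 passed with quantile normalization (-0.62, adjusted p = 0.028), median scaling (-0.65, adjusted p = 0.014), probes above background on all arrays (0.033), only the groups of the contrast (0.046) and without either Trsp-Ins1KO array (both 0.046). Selenom passed with median scaling (-0.28, adjusted p = 0.046) and normexp (-0.25, adjusted p = 0.012). Sephs2 passed with normexp (0.24, adjusted p = 0.018), probes above background on all arrays (0.04) and without Trsp-RIPKO 1 (0.86, adjusted p = 0.042), and Selenon with the mean over probes (0.41, adjusted p = 0.045). Msrb1, Selenon and Txnrd2 turned to -0.11, -0.10 and -0.22 with median scaling. Only 3 of the 15 calls (Gpx2, Gpx4 and Selenoh) held in all 6 fits that left out 1 array. Selenot was lost without TrspFF 1 (adjusted p = 0.057), Gpx1 without TrspFF 1, TrspFF 2 or Trsp-RIPKO 2 (highest adjusted p = 0.071), and the other 10 without any 1 TrspFF or Trsp-RIPKO array (highest adjusted p from 0.094 for Selenok to 0.21 for Gpx3). The same 10 were lost without the filter on dim probes (adjusted p from 0.06 for Selenok to 0.13 for Gpx3). Selenop (0.052) and Gpx3 (0.074) were lost with quantile normalization, Selenoo with normexp (0.12), and Dio1 (0.88), Gpx3 (0.05) and Selenok (0.051) with the mean over probes. Other probes gave -0.33 for Selenot, -0.08 for Selenok and 0.33 for Dio1. Selenocysteine machinery, the factors that make and insert the amino acid, showed 0 rises and 1 fall among 11 genes (camera adjusted p = 0.45). Gpx2 is also an intestinal gene, but rose more in Trsp-Ins1KO (2.01), where intestine genes rose less (median 0.71).

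**Figure D1:**
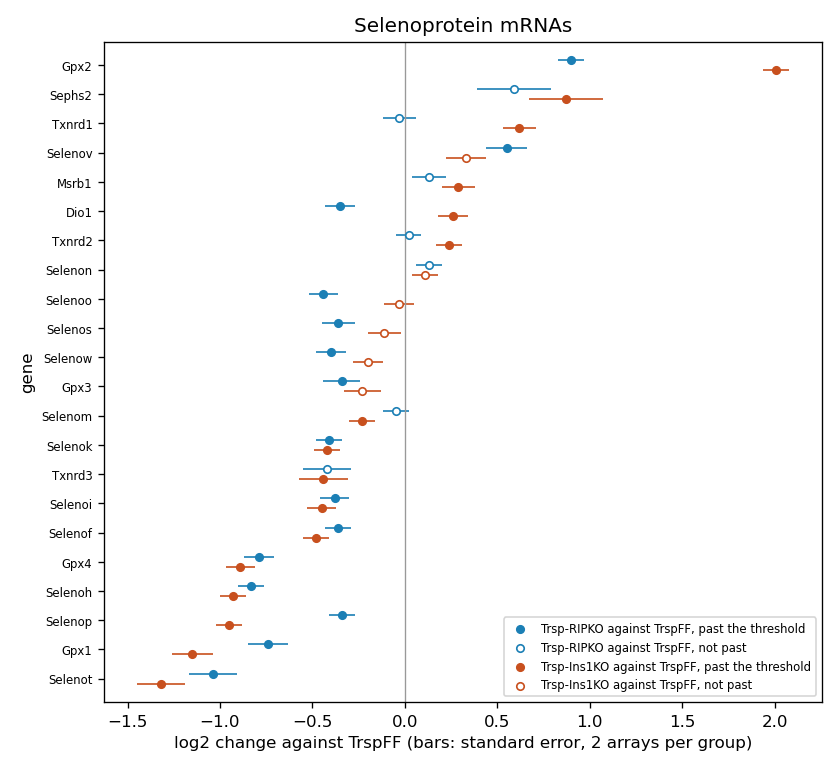
Log2 change of 22 selenoprotein mRNAs (x axis) in Trsp-RIPKO (blue) and Trsp-Ins1KO (orange) against TrspFF, with standard errors, 2 arrays per group and groups as in the scanner files; filled points passed the limma threshold. Gpx4 (-0.79 and -0.89) and Selenoh (-0.83 and -0.93) were lower in both knockouts, and Gpx2 (0.90 and 2.01) was higher in both; under the column names of the authors' table the Trsp-Ins1KO changes have the opposite sign.

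Among other redox genes, the list of antioxidant enzymes outside the selenoproteins held 10 of 27 genes that fell and 4 that rose in Trsp-RIPKO (11 and 4 adjusted over the list alone; camera adjusted p = 0.02). That call was lost with an estimated correlation (0.47), quantile normalization (0.075), median scaling (0.071) and the mean over probes (0.055). The metallothioneins Mt2 and Mt1, which bind metals, fell by 1.71 (SE 0.063) and 1.01 (SE 0.085), and Cat, encoding catalase, rose by 0.85, a call lost without TrspFF 1 or TrspFF 2 (highest adjusted p = 0.059). NRF2 targets went both ways (11 rose, 7 fell and 22 of 40 did not pass; 14 and 9 adjusted over the list alone; camera adjusted p = 0.44). Hmox1 (heme oxygenase 1) rose by 1.68, although a second probe gave 0.09, and the glutathione transferases Gstp2 and Gstm2 rose by 0.94 and 0.87, with 0.52 for a second Gstm2 probe, well above background on 1 of 2 TrspFF arrays. Nqo1 fell by 0.86, a call lost without TrspFF 1 or TrspFF 2 (highest adjusted p = 0.072).

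Mitochondrial respiratory genes fell together: 28 of 50 nuclear-encoded oxidative phosphorylation genes fell and 1 rose in Trsp-RIPKO (30 and 1 adjusted over the list alone), with a median of -0.29 (camera adjusted p = 6.1e-07, and adjusted p = 0.43 with an estimated correlation). The called examples Ndufs8 (-0.73), Cyc1 (-0.52) and Cox5a (-0.50) were each lost without TrspFF 1, TrspFF 2 or Trsp-RIPKO 2, and Cox5a also without Trsp-RIPKO 1 (highest adjusted p of 0.12, 0.095 and 0.083). Ndufs8 (0.073) and Cyc1 (0.06) were lost without the filter on dim probes. In the hypoxia and glycolysis list 11 of 25 genes fell and 1 rose (15 and 1 adjusted over the list alone; camera adjusted p = 0.016, and adjusted p = 0.59 with an estimated correlation). Bnip3, a mitophagy receptor, fell by 0.73 and Pfkfb3, a regulator of glycolysis, rose by 0.85; leaving out TrspFF 1 ended both calls, and leaving out TrspFF 2 or Trsp-RIPKO 2 ended that of Pfkfb3 (highest adjusted p of 0.05 and 0.067). Integrated stress response genes, which cells switch on when translation initiation is restrained, rose in 15 of 30 cases and fell in 1 (15 and 2 adjusted over the list alone), with a median of 0.25 (camera adjusted p = 0.0028, and adjusted p = 0.43 with an estimated correlation). Gpt2 rose by 0.91 (SE 0.084) and Sesn2 by 0.73 (SE 0.064), while Trib3 (0.84) was lost without TrspFF 1 (adjusted p = 0.054). Fgf21, counted among the 15, was well above background on no array of either group, so no change is given for it.

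Genes of hormone cells other than beta cells went both ways in Trsp-RIPKO (4 of 18 rose and 4 fell; 4 and 5 adjusted over the list alone; camera adjusted p = 0.45). Ghrl (ghrelin), Pyy and Ppy (pancreatic polypeptide) fell by 1.74, 1.10 and 1.05. Sst (somatostatin) was called at -0.27 (-0.51 with median scaling, -0.49 with quantile normalization) and lost without any 1 TrspFF or Trsp-RIPKO array (highest adjusted p = 0.20), and Gcg (glucagon) was at -0.21 (adjusted p = 0.082). Gcg passed with normexp (-0.28, adjusted p = 0.0059), quantile normalization (-0.29, adjusted p = 0.047), median scaling (-0.45, adjusted p = 0.013) and a trended robust fit (0.013). The insulin genes Ins1 (0.27, adjusted p = 0.123) and Ins2 (0.12, adjusted p = 0.313; -0.12 with median scaling) did not pass, while Ins1 did with quantile normalization (0.34, adjusted p = 0.017) and a trended robust fit (0.029). In the list of beta-cell identity 12 of 40 genes fell and 1 rose (12 and 1 also adjusted over the list alone), and the list itself missed its threshold (median -0.10, camera adjusted p = 0.056). It passed with normexp (0.015), median scaling (0.016), no filter (0.0079), the mean over probes (0.046), TrspFF arrays averaged (0.045), and without TrspFF 1 (0.034) or Trsp-RIPKO 2 (0.027). Ucn3, a marker of mature beta cells, fell by 1.21 (SE 0.114) and the channel gene Trpm5 by 0.98 (SE 0.111). Slc2a2 (the glucose transporter GLUT2, -0.62), Nkx6-1 (-0.57) and Slc30a8 (a zinc transporter of insulin granules, -0.43, or -0.66 with median scaling) were all lost without TrspFF 1. Without TrspFF 2 or Trsp-RIPKO 2, Nkx6-1 and Slc30a8 were lost too, and Slc30a8 also without Trsp-RIPKO 1 (highest adjusted p of 0.063, 0.071 and 0.086). Without the filter on dim probes, Slc30a8 (0.057) and Sst (0.14) were lost. Disallowed and dedifferentiation genes, normally silent in mature beta cells, rose in 11 of 21 cases and fell in 2 (12 and 2 adjusted over the list alone; median 0.37, camera adjusted p = 0.0034, and adjusted p = 0.43 with an estimated correlation). Cck, encoding cholecystokinin, rose by 3.38 (SE 0.141), and Neurog3, a regulator of endocrine progenitors, was called at 0.72 and lost without any 1 TrspFF or Trsp-RIPKO array (highest adjusted p = 0.07). Tph1, which starts serotonin synthesis and is under prolactin control in beta cells, rose at least 1.68-fold (adjusted p = 0.000627), but was at 0.48 with normexp. Cish, a target of STAT5, fell by 1.63 (SE 0.065) and Prlr was at 0.21 (adjusted p = 0.0527; -0.03 with median scaling). Prlr passed with quantile normalization (0.27, adjusted p = 0.029), only probes above background on all arrays (0.039), the mean over probes (0.32, adjusted p = 0.049) and a trended robust fit (0.0081). The list of growth hormone, prolactin and STAT5 response went both ways (6 rose and 8 fell of 28; 8 and 10 adjusted over the list alone; camera adjusted p = 0.80).

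Cell-cycle genes rose in 20 of 29 cases in Trsp-RIPKO and fell in 0 (21 and 0 adjusted over the list alone), with a median of 0.76, or 0.71 with genes at their bound (camera adjusted p = 9.6e-07, and adjusted p = 0.43 with an estimated correlation). Mki67, a marker of dividing cells, rose by 1.71 (SE 0.119), Mcm3 of the replicative helicase by 1.13 (SE 0.102), and Top2a at least 1.52-fold. Markers of other cells moved with them. Acinar genes rose in 25 of 29 cases and fell in 0 (28 and 0 adjusted over the list alone), with a median of 1.5 (camera adjusted p = 2.1e-14, and adjusted p = 0.41 with an estimated correlation). Among them were Reg1 (2.40), Cpb1 (2.38; well above background on 1 of 2 TrspFF arrays) and Prss1 (2.36). Fibroblast and stellate-cell genes rose in 15 of 20 cases and fell in 0 (16 and 0 adjusted over the list alone; median 0.62, camera adjusted p = 9.2e-06, and adjusted p = 0.41 with an estimated correlation). Fn1 (fibronectin) rose by 1.85 and Col1a1 by 0.95. Endothelial genes rose in 7 of 19 cases and fell in 0 (7 and 0 adjusted over the list alone; median 0.25, camera adjusted p = 0.017, and adjusted p = 0.45 with an estimated correlation). That list was lost with median scaling (0.053) and without Trsp-RIPKO 1 (0.055), and its examples Cdh5 (0.79) and Flt1 (0.61, or 0.37 with median scaling) were lost without TrspFF 1 (both adjusted p = 0.055). Erythrocyte genes fell in 4 of 7 cases (4 adjusted over the list alone; median -0.44, camera adjusted p = 0.035, and adjusted p = 0.45 with an estimated correlation), Hba-a1 by 0.89. The list call was lost with median scaling (0.11), with only probes above background on all arrays (0.051), without Trsp-RIPKO 1 (0.063) and without genes of X, Y and other tissues (0.053).

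Genes of the small intestine led the changes in Trsp-RIPKO. The 12 largest rises belonged to Defa genes, which encode alpha-defensins of Paneth cells, to the fatty-acid-binding proteins of gut and liver, and to Adh6a. Rises were at least 84.0-fold for Defa31, 46.2-fold for Defa17, 35.3-fold for Defa3, 29.0-fold for Defa26, 19.9-fold for Defa29, 14.0-fold for Defa27, 13.9-fold for Defa23, 13.1-fold for Fabp1, 11.3-fold for Defa5, 11.1-fold for Fabp2, 5.48-fold for Adh6a and 19.5-fold for Defa20. Second probes gave at least 29.5-fold for Defa3, 16.1-fold for Defa29 and 2.32-fold for Defa26, while those of Defa20 and Defa5 were well above background on no Trsp-RIPKO array. Defa genes are near-identical copies whose probes may pick up each other's transcripts. On an intestine list added after seeing the data, 28 of 35 genes rose and 1 fell (median 2.62, or 1.4 with genes not well above background in 1 group at their bound). Of that list, 15 genes were well above background in TrspFF too. The others were tested only because they were well above background in a knockout, which favours rises. Some values had been seen when the list was drawn up. Its 20 genes not seen before held 13 rises and 1 fall (median 0.90). The 12 largest falls held Mt2, Cish and Ghrl as above, Abhd17a (-2.81), Cox6a2 (-2.41), a muscle form of a cytochrome oxidase subunit, Hebp2 (-1.71; well above background on 1 of 2 Trsp-RIPKO arrays) and T2 (-1.64). They also held Slc22a29, Adgrv1, Tex11, Tbx1 and Olfr1111, which were at least 2.41-fold, 3.11-fold, 1.93-fold, 1.54-fold and 1.39-fold lower. For a second Adgrv1 probe the bound was 1.13-fold, and a second Tex11 probe was well above background on no array. Adgrv1 was lost without TrspFF 2 or Trsp-RIPKO 2 (highest adjusted p = 0.056), Olfr1111 without either TrspFF array (0.098), and Tex11 without any 1 TrspFF or Trsp-RIPKO array (0.082). Without the filter on dim probes Olfr1111 (0.06) and Tex11 (0.051) were lost.

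In limma, 3592 genes were higher and 3329 lower in Trsp-RIPKO than in TrspFF, of which 841 and 106 changed at least 2-fold by the fit, and camera called 11 lists. Probes of 6 called genes were well above background on no array of either group. Of these 6921 genes, 674 (9.7%) were called with the same sign in all 6 fits that left out 1 array: 543 higher and 131 lower. Counts of higher and lower genes were 706 and 154 without TrspFF 1, 1065 and 277 without TrspFF 2, 1618 and 1263 without Trsp-RIPKO 1, and 1037 and 513 without Trsp-RIPKO 2. With both TrspFF arrays averaged as 1 sample they were 742 and 154, and without genes of X, Y, acinar cells, liver and intestine 3456 and 3236. Median scaling gave 2013 and 7264, and normexp moved 37 of the 80 called values of named genes by over 1.5 times.

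Remaining lists in Trsp-RIPKO against TrspFF were not called. Rises and falls were 3 and 3 of 27 for the unfolded protein response (camera adjusted p = 0.68), 8 and 0 of 25 for p53 targets and apoptosis (0.26), 5 and 6 of 27 for DNA damage repair (0.59), 5 and 1 of 10 for senescence (0.16), and 3 and 9 of 23 for immediate early and heat shock genes (0.16; 0.014 with normexp). They were 4 and 5 of 25 for fatty acid oxidation (0.83), 4 and 4 of 20 for fatty acid synthesis and lipogenesis (0.66), 1 and 5 of 26 for cholesterol synthesis (0.26), 8 and 2 of 33 for the interferon response (0.24), and 4 and 2 of 18 for NF-kB and cytokine response (0.35). For 28 exocytosis and ion channel genes they were 3 and 3 (0.82), for 14 duct-cell genes 2 and 3 (0.90), for 20 macrophage and dendritic-cell genes 6 and 2 (0.30), for 7 T and B cell genes 2 and 0 (0.23), and for 10 Schwann-cell and neuron genes 1 and 1 (0.46). Median and mean differed in sign for DNA damage repair (-0.08 and 0.08), duct cells (-0.07 and 0.08), exocytosis (0.03 and -0.03) and the STAT5 list (-0.04 and 0.08), and camera ranked all 4 lower. Of the adipocyte list only 4 genes were tested, too few for a list test; Fabp4 (-0.96) and Lpl (-0.46) fell.

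In Trsp-Ins1KO islets, genes of the integrated stress response and NRF2 targets were higher than in TrspFF, liver, acinar and endothelial genes were higher, and fibroblast genes were lower. Trib3, a pseudokinase induced by ATF4, rose by 2.20 (SE 0.094, n = 2 arrays per group, limma adjusted p = 0.000533), and Gdf15, a secreted stress factor, by 2.08 (SE 0.084, adjusted p = 0.000496). Gpx1 fell by 1.15 (SE 0.108, adjusted p = 0.00255) and Gpx4 by 0.89 (SE 0.078, adjusted p = 0.00229), whereas Gpx2 rose by 2.01 (SE 0.067, adjusted p = 0.000399). Lum and Dcn, proteoglycans of connective tissue, were at least 7.64-fold lower and fell by 3.03 (SE 0.123). All of these changes have the opposite sign under the column names of the authors' table.

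Integrated stress response genes rose in 27 of 30 cases in Trsp-Ins1KO and fell in 0 (27 and 1 adjusted over the list alone), with a median of 0.85 (camera adjusted p = 1.9e-11, and adjusted p = 0.41 with an estimated correlation). Fgf21, a secreted metabolic hormone, rose at least 2.44-fold, and Nupr1 (1.96), Chac1, which degrades glutathione (1.78), Cebpb (1.53) and Atf5 (1.34) rose as well. Ddit3, which encodes CHOP, was at -0.13 (adjusted p = 0.397; -0.23 with normexp, adjusted p = 0.022). The unfolded protein response, whose PERK branch shares these genes, was not called (10 rose and 4 fell of 27; 12 and 4 adjusted over the list alone; camera adjusted p = 0.16). NRF2 targets rose in 18 of 40 cases and fell in 4 (19 and 4 adjusted over the list alone; median 0.22, camera adjusted p = 0.0035, and adjusted p = 0.43 with an estimated correlation). That list was lost with normexp (0.30) and without the filter on dim probes (0.12). Hmox1 rose by 2.54, with 0.14 for a second probe, and Gstm1, Gstm2 and Gstp2, transferases that are also abundant in liver, by 1.86, 1.81 and 1.81. Other NRF2 targets did not pass, among them Nqo1 (-0.29, adjusted p = 0.12; 0.21 with normexp) and Srxn1 (0.04, adjusted p = 0.682; -0.03 with median scaling and -0.21 with normexp). Among 27 other antioxidant enzymes 5 rose and 8 fell (also adjusted over the list alone; camera adjusted p = 0.48; called lower with normexp, 0.033, and no filter, 0.029), Cat rising by 1.39 and Mt2 and Mt1 falling by 1.38 and 1.24. Liver genes rose beside these groups in 30 of 36 cases.

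**Figure D2:**
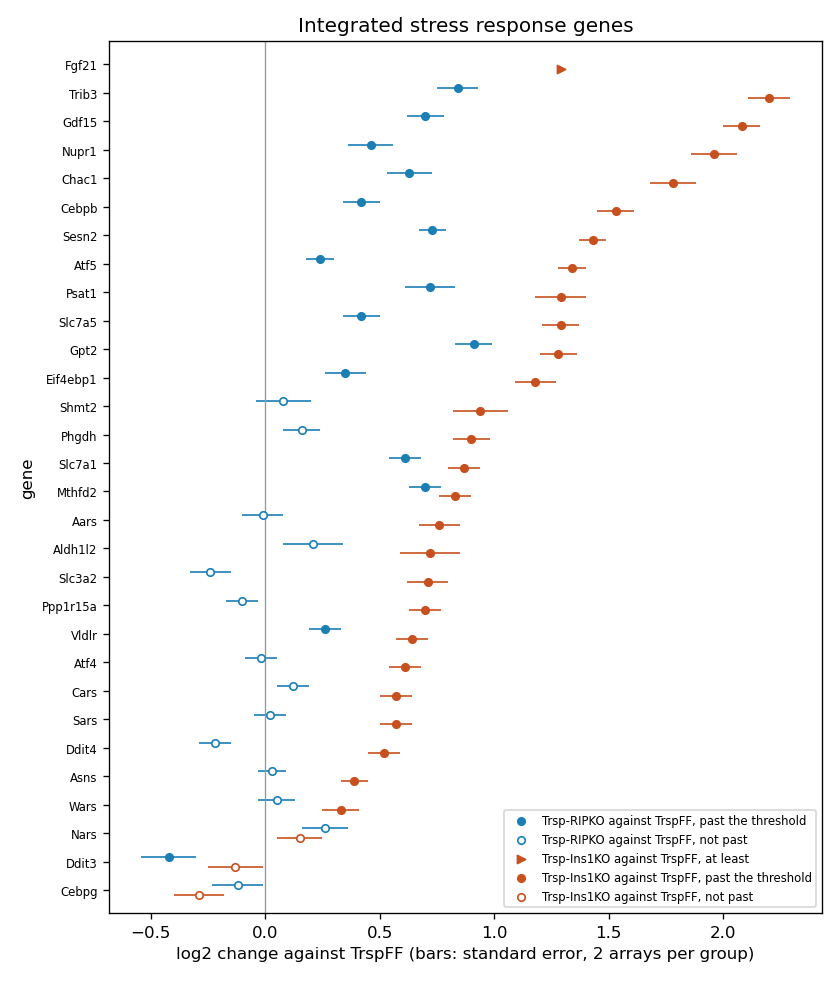
Log2 change of 30 integrated stress response mRNAs (x axis) in Trsp-RIPKO (blue) and Trsp-Ins1KO (orange) against TrspFF, with standard errors, 2 arrays per group and groups as in the scanner files; filled points passed the limma threshold, and Fgf21, not well above background in TrspFF or Trsp-RIPKO, is drawn only at its lower bound in Trsp-Ins1KO (triangle). In Trsp-Ins1KO 27 of 30 passed as higher and in Trsp-RIPKO 15; under the column names of the authors' table the Trsp-Ins1KO changes have the opposite sign.

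Among 22 selenoproteins 10 fell, 6 rose and 6 did not pass in Trsp-Ins1KO (10 and 7 adjusted over the list alone), and the list was not called (median -0.22, camera adjusted p = 0.27; called lower with normexp, 0.0047). Besides Gpx1 and Gpx4, Selenot (-1.32), Selenop, the plasma carrier of selenium (-0.95), Selenoh (-0.93), Selenof (-0.48), Selenoi (-0.45), Txnrd3 (-0.44), Selenok (-0.42) and Selenom (-0.23) fell. Besides Gpx2, rises were called for Sephs2, which makes the selenium donor (0.87), Txnrd1, the cytosolic thioredoxin reductase (0.62), Msrb1 (0.29), Dio1 (0.26) and Txnrd2 (0.24). Selenov (0.33), Gpx3 (-0.23), Selenow (-0.20), Selenos (-0.11), Selenon (0.11; -0.05 with normexp) and Selenoo (-0.03; 0.02 without TrspFF 1 and 0.04 without Trsp-Ins1KO 2) did not pass. Normexp called Gpx3 (-0.44, adjusted p = 4.6e-05), Selenow (-0.45, adjusted p = 8.7e-05) and Selenos (-0.32, adjusted p = 0.0022) lower and Selenov (0.21, adjusted p = 0.024) higher. A trended robust fit called Gpx3 (0.029), Selenow (0.029) and Selenov (0.018), and Selenov also passed with probes above background on all arrays (0.034) and without Trsp-Ins1KO 1 (0.47, adjusted p = 0.019). In all 6 fits that left out 1 array, 8 of the 16 calls held: Gpx1, Gpx2, Gpx4, Selenof, Selenoh, Selenop, Selenot and Txnrd1. Selenoi (highest adjusted p = 0.067) and Selenok (0.066) were lost without either TrspFF array, Sephs2 (0.084) also without Trsp-Ins1KO 1, and Dio1 (0.19) and Msrb1 (0.18) without any array but Trsp-Ins1KO 2. Txnrd3 (0.18) was lost without any array but Trsp-Ins1KO 1, and Selenom (0.20) and Txnrd2 (0.17) in all 6 fits. Other probes gave -0.50 for Selenot and -0.01 for Selenok, and normexp gave 0.38 for Txnrd3, 0.00 for Msrb1, 0.01 for Txnrd2 and 0.15 for Dio1. Without the filter on dim probes Dio1 (0.088), Msrb1 (0.078), Selenom (0.084), Txnrd2 (0.075) and Txnrd3 (0.065) were lost, as they were with only the groups of the contrast (adjusted p from 0.059 to 0.079). Median scaling ended the calls of Dio1 (0.2), Msrb1 (0.17) and Txnrd2 (0.19), quantile normalization those of Dio1 (0.057) and Selenom (0.072), a trended robust fit that of Txnrd3 (0.084), and the mean over probes that of Selenok (0.064). Selenocysteine machinery rose in 5 of 11 cases and fell in 1 (camera adjusted p = 0.31).

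Hormone genes separated in Trsp-Ins1KO. Ins1 (0.99), Ins2 (0.86) and Iapp, encoding islet amyloid polypeptide (0.83), rose, while Sst, Ppy and Gcg fell by 0.78, 0.68 and 0.56 (Gcg by 0.88 with quantile normalization). Before scaling, the log2 signals of Ins1 were 18.19 and 18.25 in TrspFF and 18.20 and 18.20 in Trsp-Ins1KO, and quantile normalization gave 0.18 (adjusted p = 0.06) for Ins1, 0.04 (adjusted p = 0.60) for Ins2 and 0.27 for Iapp. Genes of alpha, delta, PP and epsilon cells fell in 8 of 18 cases and rose in 1 (9 and 1 adjusted over the list alone; median -0.22, camera adjusted p = 0.02, and adjusted p = 0.43 with an estimated correlation). Ghrl fell by 1.24, and the list call was lost with the mean over probes (0.059). Beta-cell identity genes went both ways (17 rose and 10 fell of 40; 18 and 10 adjusted over the list alone; camera adjusted p = 0.27). Mafa, a transcription factor of mature beta cells, rose by 0.68 (SE 0.082), while Trpm5, Glp1r (the GLP-1 receptor), Slc30a8 and Slc2a2 fell by 1.70, 1.49, 0.75 and 0.71, with -0.69 for a second Glp1r probe. Nkx6-1 was called at 0.39 and lost without either TrspFF array (highest adjusted p = 0.092), with median scaling (0.059) and with normexp (0.48), and Ucn3 was at -0.16 (adjusted p = 0.309; -0.43 with normexp, adjusted p = 0.00046). Aldh1a3 and Cck rose by 2.02 and 1.37 in a dedifferentiation list that was not called (9 rose and 3 fell of 21, also adjusted over the list alone; camera adjusted p = 0.058). That list passed without TrspFF 2 (0.03), without Trsp-Ins1KO 2 (0.016) and without genes of X, Y and other tissues (0.028). Prlr and Cish fell by 0.68 and 0.73, with -0.06 for a second Prlr probe. Tph1 was well above background on no array of either group, so no change is given for it, although its fitted value passed. The STAT5 list was not called (10 rose, Tph1 among them, and 9 fell of 28, also adjusted over the list alone; camera adjusted p = 0.83).

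Respiratory genes fell in 31 of 50 cases in Trsp-Ins1KO and rose in 2 (32 and 2 adjusted over the list alone; median -0.27, camera adjusted p = 1.8e-05, and adjusted p = 0.47 with an estimated correlation). Cox6c fell by 0.70 (SE 0.069) and Sdhc rose by 0.66 (SE 0.074), with 0.33 for a second Sdhc probe, and Ndufs8 (-0.94) was lost without TrspFF 1 (adjusted p = 0.055). Of the p53 and apoptosis genes 10 of 25 rose and 3 fell (11 and 4 adjusted over the list alone; median 0.27, camera adjusted p = 0.037, and adjusted p = 0.43 with an estimated correlation). Cdkn1a, which encodes the cell-cycle inhibitor p21, rose by 1.37 (SE 0.064), Plk2 by 1.45 and Bbc3, a pro-apoptotic gene, by 1.14. Senescence genes rose in 5 of 10 cases and fell in 1 (the same adjusted over the list alone; median 0.86, camera adjusted p = 0.034, and adjusted p = 0.43 with an estimated correlation). Igfbp3, which binds insulin-like growth factors, rose by 1.44. The p53 list was lost with normexp (0.19), median scaling (0.051), no filter (0.37), and without TrspFF 2 (0.072), Trsp-RIPKO 1 (0.074) or Trsp-RIPKO 2 (0.078). The senescence list was lost with no filter (0.41) and without Trsp-Ins1KO 2 (0.057). Immediate early genes such as Nr4a1 (1.84), Fos (1.51) and Egr1 (1.35) rose, in a list shared with heat shock genes that was not called (10 rose and 6 fell of 23; 11 and 7 adjusted over the list alone; camera adjusted p = 0.26).

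Acinar genes rose in 22 of 29 cases in Trsp-Ins1KO and fell in 1 (25 and 2 adjusted over the list alone; median 1.28, camera adjusted p = 1.1e-09, and adjusted p = 0.43 with an estimated correlation). Cpb1, well above background on 1 of 2 TrspFF arrays, rose by 2.96, Reg1 by 2.60 and Prss2 by 1.99. Endothelial genes rose in 13 of 19 cases and fell in 1 (the same adjusted over the list alone; median 0.67, camera adjusted p = 8.1e-05, and adjusted p = 0.43 with an estimated correlation). Plvap (1.79), Cdh5 (1.70) and Flt1 (1.49) rose, and Vwf, the von Willebrand factor, fell by 3.08 (SE 0.474), well above background on 1 of 2 Trsp-Ins1KO arrays. Fibroblast genes fell in 15 of 20 cases and rose in 2 (the same adjusted over the list alone; median -0.58, or -0.52 with genes at their bound, camera adjusted p = 0.00071, and adjusted p = 0.41 with an estimated correlation), a list call lost with normexp (0.18). Col3a1 fell by 1.09 (SE 0.075), and Fbln1 was at least 1.9-fold lower but at 0.17 with normexp (adjusted p = 0.066).

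Liver genes led the rises in Trsp-Ins1KO. Major urinary protein genes rose at least 36.9-fold (Mup19), 9.82-fold (Mup4) and 4.69-fold (Mup20), Ahsg at least 18.3-fold, Alb, encoding albumin, at least 17.2-fold, and Fabp1 at least 11.6-fold. Hp (haptoglobin) rose at least 7.5-fold, Cyp2e1 at least 5.85-fold and Fgg of fibrinogen at least 4.86-fold. Slc38a1, an amino acid transporter, rose by 6.82 (SE 0.156) and Areg (amphiregulin) by 4.09, each well above background on 1 of 2 TrspFF arrays. Other Slc38a1 probes, well above background on no TrspFF array, rose at least 4.2-fold and 18.8-fold. Cyp3a11 rose at least 3.26-fold. Without the filter on dim probes Cyp3a11 was at 0.6 (adjusted p = 0.051). A second probe rose at least 23.7-fold for Mup19, and those of Mup4, Mup20 and Cyp2e1 were well above background on no array. Mup genes are near-identical copies whose probes may pick up each other's transcripts. On a liver list added after seeing the data, 30 of 36 genes rose and 0 fell (median 2.43, or 1.8 with such genes at their bound). Of that list, 17 genes were well above background in TrspFF too, and in Trsp-RIPKO 6 rose and 2 fell (median 0.18). As with the intestine list, the others entered only through a knockout, which favours rises, and some values had been seen. The 23 liver genes not seen before held 17 rises and 0 falls (median 1.07). Xist was not well above background in Trsp-Ins1KO and at least 8.27-fold lower than in TrspFF, while Ddx3y was at -0.24 (adjusted p = 0.142; -0.33 with normexp, adjusted p = 0.0013) and Eif2s3y at -0.40, a call lost without TrspFF 1 (adjusted p = 0.089). Other large falls were at least 8.29-fold for Abhd17a, 5.21-fold for Prph (peripherin of peripheral neurons), 4.61-fold for Grp, 3.79-fold for Nacad, 3.28-fold for H2-DMb1 and 2.98-fold for Igfbp6. Reep1 (at least 2.79-fold) and Smim6 (at least 2.38-fold) were lost with normexp (adjusted p = 0.077 and 0.29).

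**Figure D3:**
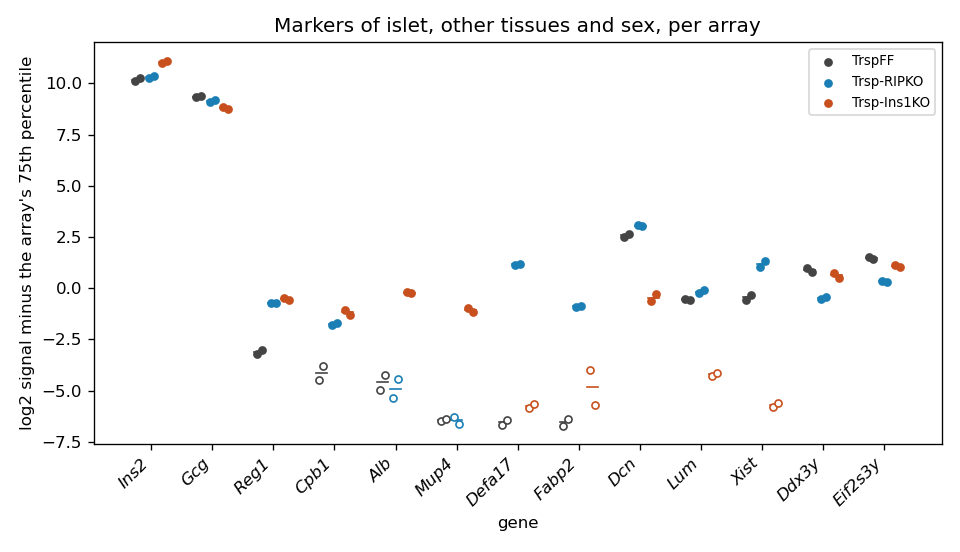
Log2 processed signal minus each array's 75th percentile (y axis) for 13 genes on the 6 arrays, grouped as in the scanner files; lines are group means of 2 arrays and open points mark groups not well above background on both arrays. Alb and Mup4 were well above background in Trsp-Ins1KO alone, Defa17 and Fabp2 in Trsp-RIPKO alone, and Xist in TrspFF and Trsp-RIPKO; under the column names of the authors' table TrspFF and Trsp-Ins1KO change places.

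In limma, 4371 genes were higher and 4366 lower in Trsp-Ins1KO than in TrspFF, of which 774 and 607 changed at least 2-fold by the fit, and camera called 9 lists. Probes of 121 called genes were well above background on no array of either group. In all 6 fits that left out 1 array, 3257 of these 8737 genes (37.3%) were called with the same sign. Counts were 1979 and 1814 without TrspFF 1, 2304 and 1978 without TrspFF 2, 2048 and 1815 with both TrspFF arrays averaged as 1 sample, 4217 and 4223 without genes of X, Y and other tissues, and 3946 and 3912 within slide 1, where both groups lay. Normexp gave 9199 higher genes, and moved 46 of the 92 called values of named genes by over 1.5 times.

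Set against Trsp-RIPKO, Trsp-Ins1KO islets had higher mRNA of stress response, NRF2, endothelial and beta-cell genes and of a list of immediate early and heat shock genes, and lower mRNA of fibroblast, cell-cycle and interferon genes. Under the names of the authors' table, these arrays filed as Trsp-Ins1KO would be TrspFF. The comparison of both knockouts then lost the list calls of beta-cell identity (0.056), exocytosis (0.84), immediate early and heat shock genes (0.16), interferon (0.23), NRF2 (0.43) and senescence (0.16). It called stress response (0.0028) and endothelial genes (0.017) lower. Stress response genes rose in 26 of 30 cases and fell in 0 (the same adjusted over the list alone; median 0.72, camera adjusted p = 2.8e-10, and adjusted p = 0.41 with an estimated correlation). Nupr1 was at 1.5 (SE 0.099, n = 2 arrays per group, limma adjusted p = 0.00121), Gdf15 at 1.38 (SE 0.084, adjusted p = 0.00106), Trib3 at 1.36 and Fgf21 at least 2.23-fold higher. NRF2 targets rose in 24 of 40 cases and fell in 3 (also adjusted over the list alone; median 0.34, camera adjusted p = 0.00018, and adjusted p = 0.43 with an estimated correlation; 0.18 with normexp). Gstm1 rose by 1.43 and Hmox1 by 0.85 (0.05 for a second probe). Among selenoproteins 4 rose and 2 fell of 22 (also adjusted over the list alone; camera adjusted p = 0.61; median -0.01 and mean 0.08). Gpx2 rose by 1.12 (SE 0.067), Txnrd1 by 0.65 (SE 0.087) and Dio1 by 0.61 (0.52, adjusted p = 0.098, for a second probe), and Selenop fell by 0.61 (SE 0.071). Gpx1 (-0.41, highest adjusted p = 0.12) was lost in 5 fits that left out 1 array, all but that without Trsp-RIPKO 2, with median scaling (-0.25), no filter (0.058) and only the groups of the contrast (0.074), and Selenoo (0.41; 0.08) without either Trsp-RIPKO array or Trsp-Ins1KO 1 and with normexp (0.07).

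Beta-cell identity genes rose in 19 of 40 cases and fell in 5 in Trsp-Ins1KO against Trsp-RIPKO (21 and 6 adjusted over the list alone; median 0.24, camera adjusted p = 0.009, and adjusted p = 0.43 with an estimated correlation). The call was lost with quantile normalization (0.15), no filter (0.17) and normexp (0.96, direction lower). Ucn3 rose by 1.06, Nkx6-1 by 0.96, Chga, encoding chromogranin A, by 0.89, Iapp by 0.88, Ins2 by 0.74 and Ins1 by 0.72, and Glp1r fell by 1.39 (-0.48, adjusted p = 0.076, for a second probe). With quantile normalization Chga came to 0.50, Iapp to 0.42, Ins2 to 0.03 (adjusted p = 0.73) and Ins1 to -0.16, and Ins1 was also lost without Trsp-RIPKO 1 (adjusted p = 0.051). Sst fell by 0.51 and Pyy rose by 1.08. Ppy (0.37) was lost in 5 fits that left out 1 array, all but that without Trsp-Ins1KO 2, and Gcg (-0.34) without TrspFF 1, TrspFF 2, Trsp-RIPKO 2 or Trsp-Ins1KO 2 (highest adjusted p of 0.11 and 0.093). Ppy was also lost with quantile normalization (0.13), no filter (0.051) and only the groups of the contrast (0.067), and Gcg, at -0.59 with quantile normalization, with median scaling (0.18) and only the groups of the contrast (0.057). Cck and Aldh1a3 fell by 2.01 and 0.84, and Prlr by 0.89 (-0.49, adjusted p = 0.055, for a second probe). Tph1 was well above background in Trsp-RIPKO and not in Trsp-Ins1KO, but too dim for a bound on its fold, and turned direction with normexp (0.29, adjusted p = 0.0033).

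Cell-cycle genes fell in 16 of 29 cases and rose in 1 (also adjusted over the list alone; median -0.54, or -0.32 with genes at their bound, camera adjusted p = 0.0013, and adjusted p = 0.43 with an estimated correlation; 0.32 with normexp). Mki67 fell by 1.63 (SE 0.119) and Ccna2 by 1.42 (-0.16, adjusted p = 0.089, with normexp). Top2a, well above background in Trsp-RIPKO alone and too dim for a bound, turned direction with normexp as Tph1 did (0.18, adjusted p = 0.046). Interferon response genes fell in 16 of 33 cases and rose in 3 (17 and 3 adjusted over the list alone; median -0.43, or -0.28 with genes at their bound, camera adjusted p = 0.0034, and adjusted p = 0.41 with an estimated correlation; 0.48 with normexp). Ifi27l2a fell by 2.29. Ifit3, also well above background in Trsp-RIPKO alone and too dim for a bound, was lost without either Trsp-RIPKO array (highest adjusted p = 0.091) and with quantile normalization (0.064), and turned direction with normexp (0.25, adjusted p = 0.0066). Immediate early and heat shock genes rose in 12 of 23 cases and fell in 1 (12 and 3 adjusted over the list alone; median 0.32, camera adjusted p = 0.0047, and adjusted p = 0.43 with an estimated correlation; 0.18 with normexp and 0.062 with no filter). Fos rose by 2.05, Hspa1a, a heat shock gene, by 1.44 and Nr4a1 by 1.40.

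Fibroblast genes fell in 16 of 20 cases and rose in 1 in Trsp-Ins1KO against Trsp-RIPKO (17 and 1 adjusted over the list alone; median -1.41, or -1.19 with genes at their bound, camera adjusted p = 8.7e-08, and adjusted p = 0.41 with an estimated correlation). Dcn fell by 3.51, and Lum and Fn1 were at least 9.98-fold and 2.83-fold lower, Fn1 with -0.11 (adjusted p = 0.25) under normexp. Endothelial genes rose in 9 of 19 cases and fell in 1 (also adjusted over the list alone; median 0.31, camera adjusted p = 0.0045, and adjusted p = 0.43 with an estimated correlation; 0.15 with no filter). Plvap rose by 1.85 and Sox18 by 1.44. Acinar genes rose in 2 and fell in 11 of 29 cases (3 and 12 adjusted over the list alone; camera adjusted p = 0.15; 0.013 with no filter and 0.039 with only probes above background on all arrays), Cela1 by 2.30. Hypoxia and glycolysis genes were called too (9 rose and 1 fell of 25, camera adjusted p = 0.029, and 0.60 with an estimated correlation). So were senescence (5 and 2 of 10, 0.035 and 0.43) and exocytosis genes (12 and 2 of 28, 0.047 and 0.43). Adjusted over the list alone, these were 9 and 1, 7 and 2, and 12 and 2. The hypoxia list was lost without Trsp-RIPKO 2 (0.068) or Trsp-Ins1KO 1 (0.14), the senescence list without Trsp-Ins1KO 2 (0.11), and the exocytosis list without Trsp-RIPKO 2 (0.059), Trsp-Ins1KO 1 (0.15) or Trsp-Ins1KO 2 (0.14). All 3 were also lost with normexp (0.75, 0.072 and 0.14) and with no filter (0.48, 0.46 and 0.46). Further losses came with median scaling for senescence (0.08) and exocytosis (0.054), and with the mean over probes (0.11) and without genes of X, Y and other tissues (0.052) for exocytosis. Hypoxia (0.078) and senescence (0.059) were lost with only probes above background on all arrays.

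Liver and intestine genes set Trsp-Ins1KO and Trsp-RIPKO apart by the largest amounts. Rises were at least 33.7-fold for Mup19, 16.7-fold for Ahsg, 16.2-fold for Alb, 8.95-fold for Mup4, 6.85-fold for Hp, 5.59-fold for Kng1, 5.34-fold for Cyp2e1, 4.28-fold for Mup20, 3.26-fold for Serpina3k, 3.13-fold for Tbx1 and 2.71-fold for Mup5, and Slc38a1 rose by 5.77. Falls were at least 45.7-fold for Defa31, 25.7-fold for Xist, 25.1-fold for Defa17, 19.2-fold for Defa3, 15.8-fold for Defa26, 10.8-fold for Defa29, 10.6-fold for Defa20, 8.23-fold for Wfdc18, 7.63-fold for Defa27, 7.57-fold for Defa23, 6.14-fold for Defa5 and 4.24-fold for Grp. Limma called 3669 genes higher and 3696 lower, 322 and 1063 of them at least 2-fold by the fit, and camera called 11 lists. Probes of 35 called genes were well above background on no array of either group. Of the 7365 genes, 3212 (43.6%) were called with the same sign in all 6 fits that left out 1 array. Counts were 2138 and 2185 without Trsp-RIPKO 1, 2069 and 2106 without Trsp-RIPKO 2, 2577 and 2775 with both TrspFF arrays averaged as 1 sample, and 3574 and 3557 without genes of X, Y and other tissues. Median scaling gave 5702 and 2351, normexp 8290 higher genes and 4 lists, and 46 of the 65 called values of named genes moved by over 1.5 times with normexp.

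Some changes from TrspFF were called the same way in both knockouts, which were set against the same 2 TrspFF arrays. Reg1 (2.40 in Trsp-RIPKO and 2.60 in Trsp-Ins1KO), Cpb1 (2.38 and 2.96, from 1 of 2 TrspFF arrays well above background) and Aldh1a3 (2.86 and 2.02) rose in both, as did Fabp1, at least 13.1-fold and 11.6-fold. Gpx4 (-0.79 and -0.89), Selenoh (-0.83 and -0.93), Mt1 (-1.01 and -1.24) and Mt2 (-1.71 and -1.38) fell in both. Calls overlapped for 1739 higher genes (825 for independent lists) and 1847 lower genes (764), while 529 genes were called in opposite directions (1589). The covariance of both sets of log2 changes across genes was 0.132, against 0.0127 simulated for unchanged groups with the same controls in 100 resamples, a difference of 0.119. Pearson's r across genes, which are not independent replicates, was 0.39 against 0.5 simulated, and 68.3% of genes had the same sign. With 2 TrspFF arrays a split would leave 1 array for each knockout, so the controls were not split, and part of the excess may come from the shared controls. Under the names of the authors' table the covariance was 0.245.

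The mean of both knockouts was higher than TrspFF for 4211 genes and lower for 4067 in limma, 582 and 167 of them at least 2-fold, and 899 of these 8278 genes (10.9%) were called with the same sign in all 6 fits that left out 1 array. Counts were 704 and 326 without TrspFF 1, 1307 and 715 without TrspFF 2, 723 and 328 with both TrspFF arrays averaged as 1 sample, 4047 and 3937 without genes of X, Y and other tissues, and 2506 and 6172 with median scaling. Camera called 9 lists. Acinar genes rose (26 of 29, 0 fell; camera adjusted p = 8.6e-13, and adjusted p = 0.41 with an estimated correlation), as did the stress response (24 of 30, 0 fell; 1.8e-09, and adjusted p = 0.41 with an estimated correlation), endothelial genes (11 of 19, 0 fell; 0.00014, and adjusted p = 0.43 with an estimated correlation) and the cell cycle (13 of 29, 0 fell; 0.00094, and adjusted p = 0.43 with an estimated correlation). Respiratory genes fell (31 of 50, 1 rose; 2.9e-07, and adjusted p = 0.43 with an estimated correlation). Dedifferentiation genes (9 rose and 1 fell of 21; 0.016, and adjusted p = 0.43 with an estimated correlation), genes of non-beta endocrine cells (1 and 7 of 18; 0.034, and adjusted p = 0.43 with an estimated correlation), NRF2 targets (15 and 4 of 40; 0.035, and adjusted p = 0.51 with an estimated correlation) and senescence genes (6 and 1 of 10; 0.038, and adjusted p = 0.43 with an estimated correlation) were called as well. Adjusted over the list alone, rises and falls were 26 and 1 for acinar genes, 27 and 1 for the stress response and 1 and 35 for respiratory genes. NRF2 targets were lost without TrspFF 2 (0.067), Trsp-RIPKO 1 (0.074) or Trsp-Ins1KO 1 (0.068), with normexp (0.43), median scaling (0.065) and the mean over probes (0.068). Non-beta endocrine genes (0.055) and senescence (0.054) were lost without Trsp-RIPKO 1, the former also with the mean over probes (0.099) and the latter with normexp (0.068). With no filter on dim probes, NRF2 (0.27), senescence (0.27) and dedifferentiation (0.077) were lost. Under the names of the authors' table, the lists of acinar cells (8.1e-05), the stress response (9.8e-12), endothelial cells (0.00029), NRF2 (0.00036) and senescence (0.027) were called lower and that of oxidative phosphorylation (0.023) higher. The cell cycle (0.2), dedifferentiation (0.56) and non-beta endocrine (0.063) calls were lost under them. Selenoproteins were not called (4 rose and 11 fell of 22; camera adjusted p = 0.071), but were with normexp (0.0027) and no filter (0.0098).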

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

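For the patterns weighed here, only the tests of intestine and liver genes were fixed ahead of their values; all others were chosen after the result had been seen. Differences between both knockouts marked the following results, each by a test of the difference itself, Trsp-Ins1KO against Trsp-RIPKO. Positive log2 medians of this difference were found for the integrated stress response (0.72), senescence (0.43), NRF2 targets (0.34), immediate early and heat shock genes (0.32), endothelial cells (0.31), beta-cell identity (0.24), exocytosis and ion channels (0.24), and hypoxia and glycolysis (0.13). Negative medians were found for fibroblasts and stellate cells (-1.41), cell cycle (-0.54) and the interferon response (-0.43; in the same order -1.19, -0.32 and -0.28 with genes at their bound), and 529 genes were called in opposite directions in both knockouts with the difference called. All 12 results take Trsp-Ins1KO from the scanner files, and under the authors' table they would compare TrspFF with Trsp-RIPKO.

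Transcripts of other tissues rose in both knockouts: Defa17 in Trsp-RIPKO, Alb in Trsp-Ins1KO and Reg1 in both. In Trsp-Ins1KO, 23 liver genes not seen before had a median log2 change of 1.07 (limit 1). As 6 entered only through a knockout, which favours rises, RNA of liver stayed open. So did RNA of intestine in Trsp-RIPKO, where 20 such genes had a median of 0.90 (0.65 at their bound), between the limits of 1 and 0.5. Acinar RNA in both knockouts stayed open too, with 72.4% of 29 tested acinar genes called higher in both. A lower share of endocrine cells in Trsp-Ins1KO was excluded as the single cause, since fibroblast markers had a median of -0.58 while acinar markers rose. A direct effect of each knockout on these genes remained the biological explanation, and none of these tests separated it from carried-over RNA.

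Xist was well above background on 4 arrays whose labels give male mice. Background or cross-hybridisation was excluded, as 2 of 2 Xist probes showed the signal on the TrspFF and Trsp-RIPKO arrays and not on Trsp-Ins1KO arrays, and a wholly female sample was excluded, as Ddx3y and Eif2s3y were well above background on all 4 arrays with Xist. A mixture of female and male RNA was consistent with the median log2 change of -0.98 for 4 Y-linked genes in Trsp-RIPKO against TrspFF. Against TrspFF, Trsp-Ins1KO had no Xist signal well above background, yet Y-linked genes went both ways there (Eif2s3y -0.40, Ddx3y -0.24, Uty 0.02 and Kdm5d 0.46, of which only Eif2s3y was called, and Ddx3y with normexp too), which did not settle whether TrspFF was mixed. No biological explanation was tested. Leaving out genes on X and Y together with those of other tissues changed no gene count by over 1.5 times. As it removed only 576 of 19021 genes, it could hardly have done so. That fit does not show whether mixed sex changed other genes.

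In the value table, the TrspFF and Trsp-Ins1KO columns match each other's scanner files. Gpx1, Selenow and Selenoh, whose mRNAs are known to fall when selenocysteine insertion fails, had a median log2 change of -0.93 in the arrays filed as Trsp-Ins1KO against those filed as TrspFF, in line with scanner files under the right group and table columns under the wrong one. In Trsp-RIPKO against the arrays filed as Trsp-Ins1KO the median was 0.10 with 1 of 3 called, which left open that the scanner files stand under the wrong group. Because transcripts of other tissues also differed, these genes alone do not settle which names are right. No biological explanation was tested for an exchange of names.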

How the results depend on the processing

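Settings other than those named above as added after seeing the data were planned. Of 40 list calls, 18 were kept in each planned refit in which they were compared, other than camera with an estimated correlation. The fit of only the groups of a contrast was not run for both knockouts against TrspFF. Of 259 values of named genes, 259 kept direction and side of the threshold with the authors' table matched to scanner files, 253 with the mean over probes, 251 with a trended robust fit, 250 with only the groups of the contrast, 244 with median scaling, 243 with quantile normalization, 235 with no filter on dim probes and 229 with normexp, as did 173 of 177 with probes above background on all 6 arrays and 32 of 46 with every probe on its own. In fits without 1 array, 1398 of 1554 did so; the lone array left in its group was assumed to vary like the others. Signal over background limited dim genes, above all in Trsp-Ins1KO. Replicates share only a number; the correlation of same-numbered deviations was 0.17, 0.28 and 0.12, and with the replicate number as a block higher and lower genes were 3539 and 3059 (Trsp-RIPKO against TrspFF), 4268 and 4221 (Trsp-Ins1KO against TrspFF), 3529 and 3521 (Trsp-Ins1KO against Trsp-RIPKO), and 4152 and 3883 (both against TrspFF), with 11, 8, 10 and 8 lists. The block ended the list calls of p53 targets in Trsp-Ins1KO (0.064), exocytosis between both knockouts (0.055) and NRF2 targets in both (0.052), and the calls of 7 named genes. No slide block was run for contrasts with Trsp-RIPKO.

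Normexp gave 9199 genes higher in Trsp-Ins1KO than TrspFF, 8290 higher than in Trsp-RIPKO, 8355 higher in both knockouts, a covariance of 0.082 and 4 lists for Trsp-Ins1KO against Trsp-RIPKO. It reversed Txnrd2 (-0.04) in Trsp-RIPKO, Selenon (-0.05), Txnrd3 (0.38), Nqo1 (0.21), Srxn1 (-0.21) and Fbln1 (0.17) in Trsp-Ins1KO, and Tph1 (0.29), Top2a (0.18) and Ifit3 (0.25) between both knockouts, all 3 not well above background in Trsp-Ins1KO. Quantile normalization reversed Txnrd1 in Trsp-RIPKO (0.03) and Ins1 between both knockouts (-0.16), and a second probe reversed Dio1 in Trsp-RIPKO (0.33). Median scaling, which shifted the median gene by -0.24, -0.08 and 0.16 in the 3 contrasts of single groups, gave 2013 higher and 7264 lower genes in Trsp-RIPKO, 5702 and 2351 between both knockouts, and 2506 and 6172 for both against TrspFF. It reversed Msrb1 (-0.11), Selenon (-0.10), Txnrd2 (-0.22), Ins2 (-0.12) and Prlr (-0.03) in Trsp-RIPKO and Srxn1 (-0.03) in Trsp-Ins1KO. With no filter, 1851 genes were higher and 841 lower in Trsp-RIPKO, 10242 higher in Trsp-Ins1KO than TrspFF, 8347 higher than in Trsp-RIPKO, and 2162 lower in both. Camera with an estimated correlation called 0 lists in each contrast, and fry 22, 20, 24 and 18. The authors' table under its own names gave a covariance of 0.245. TrspFF averaged as 1 sample gave 742 and 154 genes in Trsp-RIPKO, 2048 and 1815 in Trsp-Ins1KO and 723 and 328 in both, as fewer samples lowered the degrees of freedom. For all other changes the cause was not tested.

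Without 1 array, higher and lower genes ranged from 706 to 4068 and from 154 to 3631 in Trsp-RIPKO, from 1979 to 3997 and from 1814 to 4240 in Trsp-Ins1KO, from 2069 to 3129 and from 2106 to 3445 between both knockouts, and from 704 to 4432 and from 326 to 4426 in both. The covariance ranged from 0.11 to 0.155, and lists from 9 to 12, 8 to 11, 9 to 11 and 6 to 10. Selenoo in Trsp-Ins1KO reversed without TrspFF 1 (0.02) and Trsp-Ins1KO 2 (0.04), Txnrd1 in Trsp-RIPKO without TrspFF 2 (0.05) and Trsp-RIPKO 2 (0.01), and Srxn1 in Trsp-Ins1KO without Trsp-Ins1KO 1 (-0.01; highest value 0.09, without Trsp-Ins1KO 2).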

Other observations

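The split of immediate early from heat shock genes was chosen after their values had been seen. In Trsp-Ins1KO against TrspFF 9 of 13 immediate early genes rose and 0 fell, while 1 of 10 heat shock genes rose and 6 fell. In Trsp-RIPKO the counts were 3 and 2 for immediate early genes, and 0 and 7 for heat shock genes. Interferon response genes fell in 15 of 33 cases and rose in 4 in Trsp-Ins1KO against TrspFF (median -0.30, or -0.20 with genes at their bound), and the list missed its threshold (camera adjusted p = 0.063; 0.00027 with no filter and 0.034 without Trsp-Ins1KO 1). Cholesterol synthesis genes fell in 8 of 26 cases and rose in 3 (0.12; 0.0015 with no filter), Schwann-cell and neuron genes fell in 5 of 10 cases and rose in 1 (0.12; 0.029 with no filter and 0.037 without Trsp-Ins1KO 1), and macrophage and dendritic-cell genes rose in 8 of 20 cases and fell in 2 (0.12). Cell-cycle genes, which rose in Trsp-RIPKO, were not called in Trsp-Ins1KO (6 rose and 2 fell of 29; 0.42, or 0.015 with normexp). Of 4 tested adipocyte genes all fell in Trsp-Ins1KO: Lpl (-1.51), Fabp4 (-1.20), Cidea (-1.01) and Acvr1c (-0.34). Under the names of the authors' table, Trsp-Ins1KO against TrspFF has the opposite sign, and Trsp-RIPKO would be set against the arrays filed as Trsp-Ins1KO.

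Other lists were not called in Trsp-Ins1KO against TrspFF. Rises and falls were 9 and 2 of 28 for exocytosis and ion channels (camera adjusted p = 0.16), 0 and 3 of 7 for erythrocytes (0.26), 8 and 8 of 25 for hypoxia and glycolysis (0.83), 7 and 7 of 25 for fatty acid oxidation (0.83), and 5 and 4 of 20 for fatty acid synthesis (0.83). They were 5 and 7 of 27 for DNA damage repair (0.82), 6 and 3 of 18 for NF-kB and cytokine response (0.79), 2 and 2 of 14 for duct cells (0.84), and 1 and 0 of 7 for T and B cells (0.86). Median and mean differed in sign for hypoxia (-0.12 and 0.01), fatty acid oxidation (-0.09 and 0.10), fatty acid synthesis (-0.05 and 0.01; median 0.05 with genes at their bound), NF-kB (0.12 and -0.04) and T and B cells (0.07 and -0.04). Camera ranked hypoxia and fatty acid oxidation lower and the other 3 higher. Between both knockouts, lists not called included selenocysteine machinery (5 rose and 0 fell of 11; 0.092), other antioxidant enzymes (10 and 2 of 27; 0.092, or 0.049 without Trsp-Ins1KO 2), Schwann cells and neurons (3 and 6 of 10; 0.12, or 0.023 with median scaling and 0.03 with no filter) and oxidative phosphorylation (8 and 7 of 50; 0.90, or 2.9e-07, lower, with normexp). Median and mean differed in sign there for duct cells (0.17 and -0.05), fatty acid oxidation (0.09 and -0.18), the STAT5 list (0.10 and -0.05), macrophages (0.05 and -0.05) and NF-kB (0.04 and -0.27), camera ranking fatty acid oxidation and NF-kB lower and the others higher. Among stress response genes of log2 intensity of at least 9, 17 of 17 were higher in Trsp-Ins1KO than in TrspFF (median 0.71, SD 0.48).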
